A study of Mus musculus with 220 samples.

How the data were processed

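Single-cell RNA sequencing was done on 220 endothelial cells from lymph nodes of C57BL/6 mice. Per the labels' protocols, nodes were dissociated, blood or high endothelial cells were sorted by flow cytometry, complementary DNA was made on the Fluidigm C1 system, and libraries were built with the Nextera XT kit. The sort gate, the animals, the chips, the day of capture and the handling of doublets are not given in the sources used here. The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the cell) made by the authors, for 24049 gene symbols and 220 cells, with 2 decimals. Per the submitters' processing notes, CASAVA 1.8, RSEM 1.2.18 and the mouse build mm10 were used, and their roles and order, the annotation and any filter on cells or genes are not given in the sources used here. Of the symbols, 7527 were 0 in every cell and 94.6% were found in GENCODE release M21 (GRCm38), which supplied gene positions. Zeros made up 76.0% of all values. No mitochondrially encoded gene and no spike-in was analysed here.

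Cells were grouped by title, cell type, condition and treatment in the labels, as 32 homeostatic BEC, 79 homeostatic HEC, 65 inflamed HEC and 44 dedifferentiated HEC. All pairs of cells were compared before averaging. The inflamed cells 43 and 60 had r 0.987 on log2 values, and their log2 ratios had an SD of 0.128 over 1524 genes at an FPKM of 50 or more in both. On approximated fragment numbers the median chi-square per gene was 0.872 over 312 genes, against at least 55.2 between cell 43 and any other inflamed cell. The pair was averaged as FPKM and counted once, so that 64 inflamed HEC and 219 cells were analysed. The design written before the data were examined had all 220 cells. The limit of r above 0.9 was set after the pair had been seen.

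FPKM are not counts, so no count model was used. Depth per cell was approximated from the smallest steps of low FPKM values over 3331 single-transcript genes with the spliced length of the annotation. The lowest and highest depths were 1355230 and 3282130 fragments in BEC, 819052 and 3532430 in homeostatic HEC, 712750 and 3519500 in inflamed HEC and 794951 and 2996700 in dedifferentiated HEC. On 20 simulated cells the estimate was 0.987 to 1.01 times the true depth. Summed FPKM had medians of 469532 in BEC, 664817 in homeostatic HEC, 610269 in inflamed HEC and 651524 in dedifferentiated HEC, and no scaling between cells was added in the main values. Amplified reads without molecular tags are not independent molecules, so intervals cover counting error over cells only.

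Each GEO sample is 1 cell and no animal is named, so each group is 1 sample and no p-value, standard error or count of changed genes was computed. For each gene the mean and SD over cells of log2(FPKM + 1), computed here from the deposited FPKM, the difference of means and the share of cells at an FPKM of 1 or more with an exact Clopper-Pearson 95% interval were computed. A difference on this scale understates the ratio of low genes. The 3 main comparisons were homeostatic HEC with BEC, dedifferentiated with homeostatic HEC, and inflamed with homeostatic HEC, and both treated groups were also set against BEC. Named genes were the 12 with the largest positive and the 12 with the largest negative difference among genes at an FPKM of 1 or more in 50% of the cells of at least 1 of the groups compared. Predicted and clone names, ribosomal protein genes, haemoglobins and small RNA genes were left out, and members of fixed lists could be named in addition. Of the genes that this rule names, 1 is not reported here.

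The 18 gene lists and 12 marker lists were fixed before the data were examined. The gene lists cover sialomucins and glycosylation enzymes, adhesion molecules, chemokines, lysophospholipid metabolism, NF-kB signalling, interferon response, antigen presentation, acute inflammatory and complement genes, cell cycle, glycolysis, oxidative phosphorylation, endoplasmic reticulum, capillary lipid handling, arterial, venous, angiogenic, basement membrane and flow-responsive genes. The marker lists cover blood, high and lymphatic endothelial cells, pericytes, fibroblastic reticular cells, T and B lymphocytes, leukocytes in general, myeloid cells, erythroid cells, platelets and dissociation with heat shock. In the lists, 6 symbols had no match in the table. Members at an FPKM of 1 or more in 10% of cells or fewer of both groups were left out of medians. Each median was placed among the medians of 10000 random lists of the same size, matched on mean level in 10 bins. Lists with fewer than 3 members got no percentile.

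The position between HEC and BEC used the 50 genes with the largest difference in each direction, chosen on odd-numbered cells and measured on even-numbered homeostatic cells and all treated cells. Nearest groups were found with the cell left out, by Pearson correlation over the 2000 genes of largest variance. Cells were said to carry markers of another type at 3 or more markers of a list with an FPKM of 10. The coefficient of variation was computed on FPKM. No cells were removed in the main values, no clusters were made and no doublet caller was run. To look for a hidden batch that follows the cell number, cells of each group were split into a lower-numbered and a higher-numbered part. The labels do not say that the number follows chip or day, so this split cannot detect a batch that does not follow it. The 99th percentile of gene differences was 2.49 in BEC, 1.51 in homeostatic HEC and 1.68 in inflamed HEC, inside the range over 30 random splits in each of them (2.41 to 3.03, 1.45 to 1.76 and 1.57 to 1.91), and 2.26 in dedifferentiated HEC (2.14 to 2.49).

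Alternatives were pseudocounts of 0.1 and 10, no filter and a stricter filter on list members, rescaling of each cell to a common total or by median ratios over 607 genes, ratios of arithmetic means, leaving out cells over 3 median absolute deviations from the group's number of genes or with markers of another type, odd- or even-numbered cells alone, other detection limits, other numbers of genes, and, chosen after seeing the data, cells matched on 2500 to 4000 detected genes, totals without Glycam1 and Ccl21a, and the near-identical cells kept apart. Matching narrowed the gaps in gene number without closing them. The median number of detected genes in matched cells was 3011 in BEC, 3422 in homeostatic HEC, 3541 in inflamed HEC and 3151.5 in dedifferentiated HEC. The calculation was tested on simulated data with 200 genes changed by a factor of 4. The direction was recovered for 199 of 200 among 1849 genes in the setting of HEC and BEC. It was recovered for 200 of 200 among 2552 genes in each of the other main comparisons. The changed cells were redrawn from the reference group itself, so the simulation held no difference of animal, chip or gene number between groups. Unchanged genes had a 99th percentile of absolute difference of 0.966 for HEC with BEC, 0.990 for dedifferentiated and 0.797 for inflamed with homeostatic HEC. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.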

Results

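Transcript levels were measured by single-cell RNA sequencing in endothelial cells sorted from lymph nodes of C57BL/6 mice. Each of the 220 cells had its own library, made after capture on the Fluidigm C1 system. There were 32 blood endothelial cells (BEC) and 79 high endothelial cells (HEC) of untreated mice, called homeostatic, 65 inflamed HEC and 44 dedifferentiated HEC. High endothelial cells form the walls of the venules through which lymphocytes leave the blood and enter the node. Inflamed HEC came from mice whose skin was painted with 4% oxazolone, a contact sensitiser, and were taken on day 3. Dedifferentiated HEC were taken on day 7 after 1 intraperitoneal injection of LTBR-Ig, a soluble form of the lymphotoxin β receptor that captures its ligands. The inflamed cells 43 and 60 had near-identical profiles (Pearson r 0.987 on log2 values, against 0.666 for the next closest of all pairs of cells). On approximated fragment numbers their median chi-square per gene was 0.872, against at least 55.2 between cell 43 and any other inflamed cell. Cells 43 and 60 were averaged and counted as 1 cell, which left 64 inflamed HEC and 219 cells in all.

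A median of 2871 genes reached an FPKM of 1 in the BEC, 3842 in the homeostatic HEC, 3961 in the inflamed HEC and 3075 in the dedifferentiated HEC. The depth, approximated from the step sizes of low FPKM values, had medians of 2013830 fragments in BEC, 1833730 in homeostatic HEC, 2147960 in inflamed HEC and 2131890 in dedifferentiated HEC. Glycam1 and Ccl21a together took a median of 20.8% of the summed FPKM of a homeostatic HEC, 4.06% in inflamed HEC, 11.8% in dedifferentiated HEC and 0.029% in BEC. No animal, pool, chip or sort gate is named for any cell, so each group counted as 1 sample: there is no replicate check, no p-value and no count of changed genes. Group, chip and day of harvest cannot be told apart. Differences below are differences of mean log2(FPKM + 1), an SD is the spread over cells, and intervals are exact Clopper-Pearson 95% intervals that cover counting error over cells only. A list member counted as higher or lower at a difference of 1 or more. Genes below an FPKM of 1 in 90% or more of the cells of both groups were left out of list medians.

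The comparison of HEC with BEC asks which transcripts set the specialised venule cells apart from the other blood vessel cells of the node. Homeostatic HEC were far higher in Glycam1 and Ccl21a. Glycam1, a secreted sialomucin that carries L-selectin ligands, averaged 15.13 ± 2.40 in HEC and 6.22 ± 0.89 in BEC (mean ± SD, n = 79 and 32), a difference of 8.91. Ccl21a, a chemokine that recruits naive lymphocytes, averaged 14.70 ± 2.89 and 5.83 ± 0.70, a difference of 8.88. Cxcl12, a chemokine of stromal and capillary cells, went the other way, with 1.49 ± 2.25 in HEC and 8.61 ± 1.77 in BEC.

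Among the sialomucins and glycosylation enzymes of L-selectin ligands, 7 of 15 members were higher and 1 was lower in HEC. The enzymes Fut7 (fucosyltransferase, 6.64), Chst4 (sulfotransferase, 6.39), Gcnt1 (core branching enzyme, 6.09), Chst2 (3.12), B3gnt3 (1.84) and St3gal6 (1.21) were higher. St3gal6 turned to -0.14 as a ratio of arithmetic means and to -0.18 in cells matched on the number of detected genes. Podxl was lower by the same measure, at -4.25, and Cd34, a sialomucin of both cell kinds, was at 0.46. Chst4 reached an FPKM of 1 in 74 of 79 HEC (93.7%, interval 85.8% to 97.9%) and in 3 of 32 BEC (9.38%, 1.98% to 25%). The genes lie on different chromosomes in GRCm38: Glycam1 at 103562759 to 103565081 of chromosome 15, Ccl21a at 42772860 to 42773993 of chromosome 4, Fut7 at 25423267 to 25426374 of chromosome 2, Chst4 at 110029153 to 110039740 of chromosome 8, Gcnt1 at 17326141 to 17372844 of chromosome 19 and Cxcl12 at 117168535 to 117181367 of chromosome 6. Ccl21a has near-identical copies, and the share of its reads that belongs to Ccl21b, itself higher in HEC by 2.82, is uncertain. Low levels of abundant HEC transcripts were present in every BEC: Glycam1 lay between an FPKM of 32.8 and 594.2 in all 32 BEC, and Ubd had a mean FPKM of 28.8 there.

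The other genes furthest above BEC were Pglyrp1, an antibacterial peptidoglycan-binding protein (8.77), Ubd, a ubiquitin-like protein induced by cytokines (7.97), Ackr1, the atypical chemokine receptor of venules (7.34), Serpina1e (7.24), Dclk1 (6.94), Lrg1 (6.85), Oit1 (6.76) and Spint2 (6.51). Those furthest below were Rgcc (-7.31), Gpihbp1, which anchors lipoprotein lipase on capillaries (-7.08), Rbp7 (-6.88), Ly6c1 (-6.15), Slc9a3r2 (-5.34), the fatty acid receptor Cd36 (-5.34), Pcp4l1 (-5.27), Itm2a (-5.12), the endothelin receptor Ednrb (-5.04), Sparcl1 (-4.89) and Thbd, the thrombin receptor thrombomodulin (-4.76).

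The median of all 9248 genes that were not little detected was 0.28 higher in HEC, and list medians are given below relative to the median of all genes. Each also has its percentile among 10000 random lists of the same size and level, which only describes these cells. Lymphotoxin receptor and NF-kB signalling lay 1.24 above (percentile 100), with 10 of 16 members higher and none lower, among them Birc2 (2.73), Nfkbia (2.32), Nfkb2 (2.17), Tnfaip3 (2.16) and Relb (2.12). The receptor Ltbr itself was at -0.24 and Nfkb1 at 0.10. Acute inflammatory and complement genes lay 3.80 above (percentile 100), with 7 of 8 members higher, after 11 of 19 measured members were left out as little detected in both groups. The higher members included the complement genes C1s1 (5.18), Cfb (5.12) and C1ra (3.57) and the cytokine receptors Il6st (4.59) and Il1r1 (2.50). Venous genes lay 2.39 above (percentile 100), with 9 of 11 higher, such as the venous regulator Nr2f2 (3.43) and Vwf (2.48). Endoplasmic reticulum chaperones and secretion genes lay 0.80 above (percentile 86.1), with 12 of 21 higher, including Xbp1 (3.26), Sec61b (3.23), P4hb (2.75), Calr (2.15) and Hspa5 (2.02). The dissociation and heat shock markers moved with these lists: 10 of 14 were higher in HEC, 1.51 above the median of all genes, among them Ier3 (4.54), Fos (3.93) and Egr1 (3.42).

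Most arterial and angiogenic genes that were not little detected, and some capillary genes, were lower in HEC. Arterial and Notch genes lay -1.57 from the median of all genes (percentile 0.00), with 8 of 12 lower, including Efnb2 (-3.63), Gja4 (-2.58) and Sox17 (-2.23). Angiogenic genes lay at -1.81 (percentile 0.00), with 8 of 14 lower, including Esm1 (-3.67), Flt1 (-3.22), Nrp1 (-2.95) and Kdr (-2.77), while Angpt2 was higher by 1.70. Capillary lipid handling lay at -0.83 (percentile 0.02), with 5 of 13 lower, among them Car4 (-1.99) and Fabp4 (-1.19, but 0.33 in even-numbered cells alone). Basement membrane and matrix genes lay at -0.68 (percentile 0.12), with 7 of 15 lower, including Col4a1 (-2.42), Sparc (-2.41) and Col4a2 (-2.32). The blood endothelial markers lay at -0.93 (percentile 0.00), with 4 of 12 lower, and the flow-responsive and inflammatory-restraint genes at -0.52 (percentile 1.32), with Klf4 at -1.14.

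Lymphocyte entry adhesion molecules lay 0.49 above the median of all genes (percentile 49.8), with 5 of 14 higher, among them the tetraspanin Cd63 (6.03), the integrin ligands Icam1 (4.75) and Vcam1 (2.06) and P-selectin, Selp (2.67). Jam2 was lower, at -1.33, and Madcam1 was at 0.21. Chemokines lay 0.30 above (percentile 92.9), with Cxcl1 at 3.97 and Cx3cl1 at -1.53. Lysophospholipid and sphingosine 1-phosphate genes went both ways, with 3 of 9 higher and 4 lower and a median 0.14 above: Enpp2, which makes lysophosphatidic acid, was higher by 4.25 and the exporter Spns2 by 1.49, whereas the phosphatases Ppap2b (-4.26) and Ppap2a (-3.91) were lower. Interferon response genes lay at -0.06 (percentile 5.52), with 3 of 23 higher and 5 lower, the latter including Rsad2 (-4.55), Ifit3 (-2.42) and Irf7 (-1.66). Antigen presentation lay 0.29 above (percentile 35.9), with 6 of 18 higher, including the class II genes Cd74 (5.17) and H2-Aa (2.32), and 2 lower. Oxidative phosphorylation lay 0.62 above (9 of 20 higher, percentile 55.1), glycolysis 0.39 above (5 of 14 higher, percentile 64), with Pkm at 2.24 and Gapdh at 1.71, and the cell cycle at -0.42 (1 of 9 higher, percentile 5.56).

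At 3 or more markers of a type with an FPKM of 10, markers of other cell types were present in 1 of 32 BEC (3.13%, 0.079% to 16.2%) and 7 of 79 homeostatic HEC (8.86%, 3.64% to 17.4%), in HEC mainly B lymphocyte and pan-leukocyte genes. When 2 markers sufficed, it was 10 of 32 BEC (31.3%), 9 of them by the lymphatic list, which holds Ccl21a, and 14 of 79 HEC (17.7%). Pf4, a platelet chemokine, was higher in HEC by 3.40 and the leukocyte gene Coro1a by 1.71, with the pan-leukocyte list 0.25 above the median of all genes. The other 4 platelet markers were little detected, and 0 of 79 HEC carried 3 platelet markers at an FPKM of 10. The lymphatic gene Flt4 was lower, at -1.73, and the lymphatic list lay 0.05 above. The few measured members of the pericyte (-0.51), fibroblastic reticular (0.33), T lymphocyte (-0.42) and B lymphocyte (0.25) lists all lay between the bounds, and myeloid and erythroid markers were little detected. Within a group, odd- and even-numbered cells differed by up to 2.76 in BEC and 1.58 in homeostatic HEC for 99% of genes, so a difference near 1 lay within the spread of cell sampling.

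**Figure D1:**
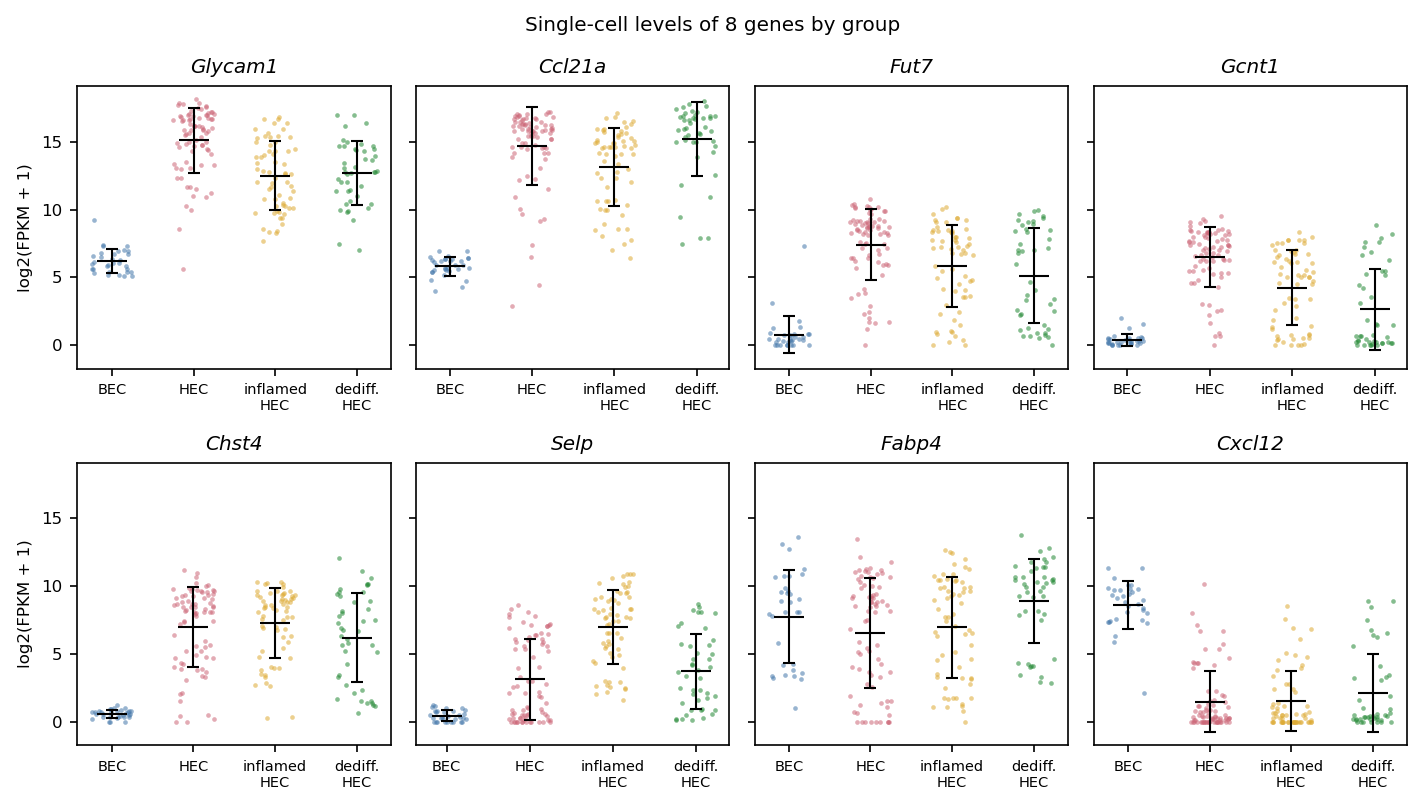
Level of 8 genes as log2(FPKM + 1) in each cell (points) of the 4 groups, with the mean and SD over cells (black line and bars; n = 32, 79, 64 and 44). Gcnt1 averaged 6.50 in homeostatic HEC, 4.25 in inflamed HEC, 2.66 in dedifferentiated HEC and 0.41 in BEC, and Selp averaged 6.98 in inflamed HEC.

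Dedifferentiated HEC were compared with homeostatic HEC to see which transcripts differ when lymphotoxin receptor ligands are captured. Gcnt1, Glycam1 and Fut7 were lower while the chemokine Ccl21a was not. Gcnt1 averaged 2.66 ± 2.99 in dedifferentiated and 6.50 ± 2.22 in homeostatic HEC (mean ± SD, n = 44 and 79), a difference of -3.84, and reached an FPKM of 1 in 21 of 44 cells (47.7%, 32.5% to 63.3%) against 75 of 79 (94.9%, 87.5% to 98.6%). Glycam1 averaged 12.71 ± 2.33 against 15.13 ± 2.40, lower by the same measure at -2.42, and Fut7 5.14 ± 3.49 against 7.42 ± 2.62, at -2.29. Ccl21a averaged 15.21 ± 2.70 against 14.70 ± 2.89, a difference of 0.50, and Fabp4, a fatty acid binding protein of capillaries, was higher by 2.36.

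The sialomucin and glycosylation list had 3 of 15 members lower (Gcnt1, Glycam1 and Fut7) and none higher, and lay at -0.18 from the median of all genes (percentile 23.3), but above the median of -0.56 over the 2878 genes that reached an FPKM of 1 in 50% of the cells of either group. Chst4 (-0.77) and Chst2 (-0.76) differed less. Chst4 reached an FPKM of 1 in 43 of 44 cells (97.7%, 88.0% to 99.9%), a share that depends on this low limit. Its median FPKM was 105.2 in dedifferentiated against 274.6 in homeostatic HEC, while its mean FPKM was 417.5 against 394.6. The list median before subtraction, -0.48, turned to 0.04 in cells matched on gene number and to 0.11 as ratios of arithmetic means. Of the high endothelial markers, 3 of 7 were lower, with a list median at -0.47 (percentile 15.1).

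Other genes furthest below homeostatic HEC were Ly6i (-4.59), Tmed3, a cargo receptor of the secretory pathway (-3.86), the neutrophil chemokine Cxcl1 (-3.86), Oit1 (-3.40), Egr1 (-3.36), Pf4 (-3.20), Ube2l6 (-2.97), Cd247 (-2.82), Sec11c, a subunit of signal peptidase (-2.82), Pgrmc2 (-2.75) and Ms4a6b (-2.75). Among those furthest above were Fabp4 (2.36), the lipid carrier Apoe (2.34), Fabp5 (2.30), Syt15 (2.19), Nmt2 (2.13), Vwf (1.98), Mustn1 (1.90), the water channel Aqp1 (1.89), Arrdc1 (1.88), Cdc42ep2 (1.83) and Fcgrt (1.67). Fabp5 reached an FPKM of 1 in 37 of 44 dedifferentiated (84.1%, 69.9% to 93.4%) and 36 of 79 homeostatic HEC (45.6%, 34.3% to 57.2%).

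The median of all 9008 genes that were not little detected was -0.30 (-0.21 after rescaling by median ratios, -0.12 in cells matched on gene number, -0.027 with arithmetic means, and -0.48 and -0.10 with pseudocounts of 0.1 and 10), and lists are given relative to it. Lymphotoxin receptor and NF-kB signalling lay at -0.41 (percentile 1.43), with 5 of 16 lower and 1 higher: Tnfaip3 (-1.88), Birc3 (-1.74), Nfkb2 (-1.73), Nfkbie (-1.18) and Ubd (-1.08) were lower, Relb was at -0.91, and the tumour necrosis factor receptor Tnfrsf1a was higher by 1.43. Complement genes C1s1 (-2.48), Cfb (-1.80) and C1ra (-1.69) were lower and Lrg1 was higher by 1.48. The acute inflammatory and complement list, with 4 of 11 members lower, 1 higher and 6 between, lay 0.63 above (percentile 99.98). Of the dissociation and heat shock markers, 5 of 14 were lower, with a median at -0.15 (percentile 45.7): Fos (-2.51), Egr1 and Ier2 (-1.63) were lower, while Jun was at 0.48 and Dusp1 at 0.34.

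Capillary lipid handling lay 0.64 above (percentile 99.99), with Fabp4, Fabp5, Aqp1 and Car4 (1.55) higher among 11 members. Car4 reached an FPKM of 1 in 32 of 44 cells (72.7%, 57.2% to 85.0%) against 7 of 79 (8.86%, 3.64% to 17.4%), but at low levels, and turned to -0.53 as a ratio of arithmetic means. The capillary genes Gpihbp1 (0.32), Cd36 (-0.37) and Rgcc (-0.86) were not higher by 1. Angiogenic genes lay 0.65 above (percentile 99.98), with Aplnr (1.40), the angiopoietin receptor Tek (1.23) and Nrp2 (1.13) higher among 11. The blood endothelial markers lay 0.80 above (percentile 100), with 1 of 12 higher and Pecam1 at 0.82. Venous genes lay 0.50 above (percentile 99.8), with Vwf and Lrg1 higher, and flow-responsive genes 0.42 above (percentile 99.5), with 1 of 11 lower.

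Adhesion molecules of lymphocyte entry lay 0.42 above (percentile 99.8): Jam3 was lower, at -1.99, and Ackr1 (0.18), Icam1 (-0.60), Vcam1 (-0.83) and Madcam1 (-0.29) were not. Chemokines lay at -0.16 (percentile 18.6), with Cxcl1 lower. Lysophospholipid genes lay 0.31 above (percentile 97.7), with Enpp2 at -0.53 and Sphk1 at -1.14, the latter listed at 0 in all 44 cells. Interferon response genes lay at -0.12 (percentile 52.2), with 4 of 23 lower, including Rtp4 (-1.17) and Irf7 (-1.15), and antigen presentation 0.27 above (percentile 99.3), with Cd74 at -1.45. Oxidative phosphorylation (-0.24, percentile 38, Cycs at -2.05 and Sdhb at -1.31), endoplasmic reticulum genes (0.03, percentile 86.8, Hspa5 at -1.29), glycolysis (0.01, percentile 75.3), arterial and Notch genes (0.03, percentile 56), basement membrane genes (0.11, percentile 87.3, Nid1 at -1.61) and the cell cycle (-0.24, 8 members, percentile 10.1) had few members past 1.

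Markers of another cell type were present in 2 of 44 dedifferentiated HEC (4.55%, 0.555% to 15.5%), and in 6 of 44 when 2 markers sufficed. The pan-leukocyte list lay at -0.21 (percentile 1.42), with Coro1a past -1, and the T lymphocyte list 0.30 above (percentile 84.2). The measured B lymphocyte (-0.26), pericyte (0.40), fibroblastic reticular (-0.37), lymphatic (0.51) and erythroid (0.44) markers had no member past 1, and myeloid markers were little detected.

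Inflamed HEC were compared with homeostatic HEC to see which transcripts differ on day 3 after a skin sensitiser. Selp, 12 of 23 interferon and 9 of 14 basement membrane genes were higher, and Glycam1 and 8 of 14 dissociation and heat shock markers were lower. Selp, P-selectin, averaged 6.98 ± 2.71 in inflamed and 3.12 ± 2.96 in homeostatic HEC (mean ± SD, n = 64 and 79), a difference of 3.86, and reached an FPKM of 1 in 64 of 64 cells (100%, 94.4% to 100%) against 46 of 79 (58.2%, 46.6% to 69.2%). Glycam1 averaged 12.50 ± 2.54 against 15.13 ± 2.40, a difference of -2.62. Fos, an immediate early transcription factor, averaged 3.42 ± 3.69 against 7.75 ± 2.98, a difference of -4.33.

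The genes furthest above homeostatic HEC, besides Selp, were S100a11, a calcium-binding protein (4.01), Mcam, a melanoma-associated adhesion molecule (3.58), Mctp1 (3.56), Mustn1 (3.37), the insulin receptor Insr (3.36) and Emp1 (3.13). They were followed by Ch25h, which makes an oxysterol (3.07), Nudt4 (2.91), the prostaglandin transporter Slco2a1 (2.88), Anxa1 (2.83) and the collagen Col18a1 (2.76). Besides Fos, those furthest below were Egr1 (-4.07), Ppp1r15a (-3.70), Zfp36, which destabilises cytokine messages (-3.67), Cxcl1 (-3.49), Kctd12 (-3.29), Gm2a (-3.19), Sult1a1 (-3.14), the class II chaperone Cd74 (-3.07), the phospholipid transfer protein Pltp (-3.01), the clotting factor F8 (-2.81) and Jam3 (-2.78).

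The median of all 9525 genes that were not little detected was 0.10. Interferon response genes lay 1.06 above it (percentile 100), with 12 of 23 higher and none lower, among them Oasl2 (2.19), Bst2 (2.06), Ifit3 (1.89), Gbp7 (1.82), Irf7 (1.78) and Isg15 (1.68). Basement membrane and matrix genes lay 1.09 above (percentile 100), with 9 of 14 higher and none lower, including Col18a1, Col4a2 (2.20), Sparc (2.06), Col4a1 (1.74) and Nid1 (1.46). The interferon median of 1.17 was 0.44 as ratios of arithmetic means and 0.53 in even-numbered cells alone, and the matrix median of 1.19 was 0.56 with a pseudocount of 10.

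Cell cycle genes lay 0.54 above (percentile 100) and all 19 members that were not little detected were higher in the mean, 3 of them by 1 or more: Cdk1 (1.06), Mcm5 (1.05) and the cyclin Ccnb2. The other 5 members were left out as little detected in both groups. With dedifferentiated in place of inflamed HEC only 8 members passed this filter. Most of the 19 therefore passed it through inflamed HEC alone, where a higher mean was then close to given. The mitotic gene Top2a reached an FPKM of 1 in 21 of 64 inflamed HEC (32.8%, 21.6% to 45.7%), 3 of 79 homeostatic HEC (3.80%, 0.79% to 10.7%), 0 of 44 dedifferentiated HEC and 0 of 32 BEC, counts of 0 that allow up to 8.04% and 10.9%. Cdk1 did so in 17 of 64 inflamed HEC (26.6%, 16.3% to 39.1%) and 1 of 79 homeostatic HEC (1.27%, 0.032% to 6.85%), and the proliferation marker Mki67 in 16 of 64 (25%, 15% to 37.4%) and 6 of 79 (7.59%, 2.84% to 15.8%). Glycolysis genes lay 0.64 above (percentile 99.9), with 4 of 14 higher, including Pgk1 (1.74), Pgam1 (1.53) and Ldha (1.47).

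Of the sialomucin and glycosylation genes, 5 of 15 were lower and 2 higher, with the list at -0.10 (percentile 22.9). Glycam1, Gcnt1 (-2.25), Fut7 (-1.58), St3gal6 (-1.33) and Chst2 (-1.12) were lower, B3gnt3 (1.53) and Podxl (past 1) were higher, and Chst4 was at 0.32. The high endothelial markers lay at -1.48 (percentile 0.01), with 6 of 8 lower: Ccl21a was at -1.53, but at 0.04 in even-numbered cells alone, and Enpp2 was at -1.22. Madcam1, the mucosal addressin, was higher by 1.22 and reached an FPKM of 1 in 18 of 64 cells (28.1%, 17.6% to 40.8%) against 5 of 79 (6.33%, 2.09% to 14.2%).

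Adhesion molecules of lymphocyte entry lay 0.38 above (percentile 96.5), with 4 of 15 higher and 2 lower. Selp, Cd47 (1.99), E-selectin, Sele (1.75), and Madcam1 were higher, Jam3 and Cd63 (-1.09) were lower, and Icam1 (-0.36) and Vcam1 (-0.15) lay between. Sele reached an FPKM of 1 in 33 of 64 inflamed (51.6%, 38.7% to 64.2%) and 20 of 79 homeostatic HEC (25.3%, 16.2% to 36.4%). Chemokines lay at -0.31 (percentile 5.03), with Cxcl9, a chemokine of interferon-γ responses, higher by 2.19 and Cxcl1 and Ccl21a lower. Cxcl9 reached an FPKM of 1 in 44 of 64 inflamed (68.8%, 55.9% to 79.8%) and 24 of 79 homeostatic HEC (30.4%, 20.5% to 41.8%). Antigen presentation went both ways, 0.11 above (percentile 64.9), with Psme2 (1.36) and Tap2 (1.33) higher and the class II genes Cd74, H2-Aa (-1.79) and H2-DMa (-1.04) lower.

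Lymphotoxin receptor and NF-kB signalling lay at -0.18 (percentile 10.5), with Ltbr (1.88) and Tnfrsf1a (1.29) higher and Nfkbia (-1.21) and Tnfaip3 (-1.18) lower among 16. Acute inflammatory and complement genes lay 0.16 above (percentile 78.9), with Serpina3n (1.58) and Lrg1 (1.43) higher. Venous genes lay 0.52 above (percentile 96.9) with 4 of 11 higher, angiogenic genes 0.27 above (percentile 91.8), flow-responsive genes at -0.02 (percentile 41.9) with the transglutaminase Tgm2 (2.42) and Thbd (1.16) higher, and blood endothelial markers 0.24 above (percentile 83.7). Capillary lipid handling lay 0.22 above (percentile 93.6), with Aqp1 (1.56) higher and Cd300lg (-1.75) lower. Lysophospholipid genes lay at -0.04 (percentile 37.3), with Spns2 higher by 1.23, and oxidative phosphorylation (0.17, percentile 76.1), endoplasmic reticulum genes (0.15, percentile 76.3) and arterial and Notch genes (0.02, percentile 53.8) lay near the median of all genes.

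The dissociation and heat shock markers lay at -1.62 (percentile 0.00), with 8 of 14 lower: Jun (-2.38) and Dusp1 (-2.23) were lower besides Fos, Egr1 and Zfp36. The NF-kB targets Nfkbia and Tnfaip3 and the chemokine Cxcl1 were lower in the same cells. Markers of another cell type were present in 3 of 64 inflamed HEC (4.69%, 0.977% to 13.1%), and in 22 of 64 when 2 markers sufficed, in 20 of them lymphatic, a list that also holds Ccl21a. Lyve1, a lymphatic marker, was higher by 1.54 and reached an FPKM of 1 in 20 of 64 cells (31.3%, 20.2% to 44.1%) against 9 of 79 (11.4%, 5.34% to 20.5%), and the platelet gene Pf4 was at -2.20. The pan-leukocyte list lay at -0.42 (percentile 0.57), the T lymphocyte list 0.14 above (percentile 76.5), and the measured B lymphocyte (-0.39), lymphatic (-0.10), pericyte (-0.17), fibroblastic reticular (-0.09), myeloid (-0.14) and platelet (-1.06) markers rested on 1 or 2 genes each. Odd- and even-numbered cells of 1 group differed by up to 1.75 in inflamed and 2.10 in dedifferentiated HEC for 99% of genes.

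**Figure D2:**
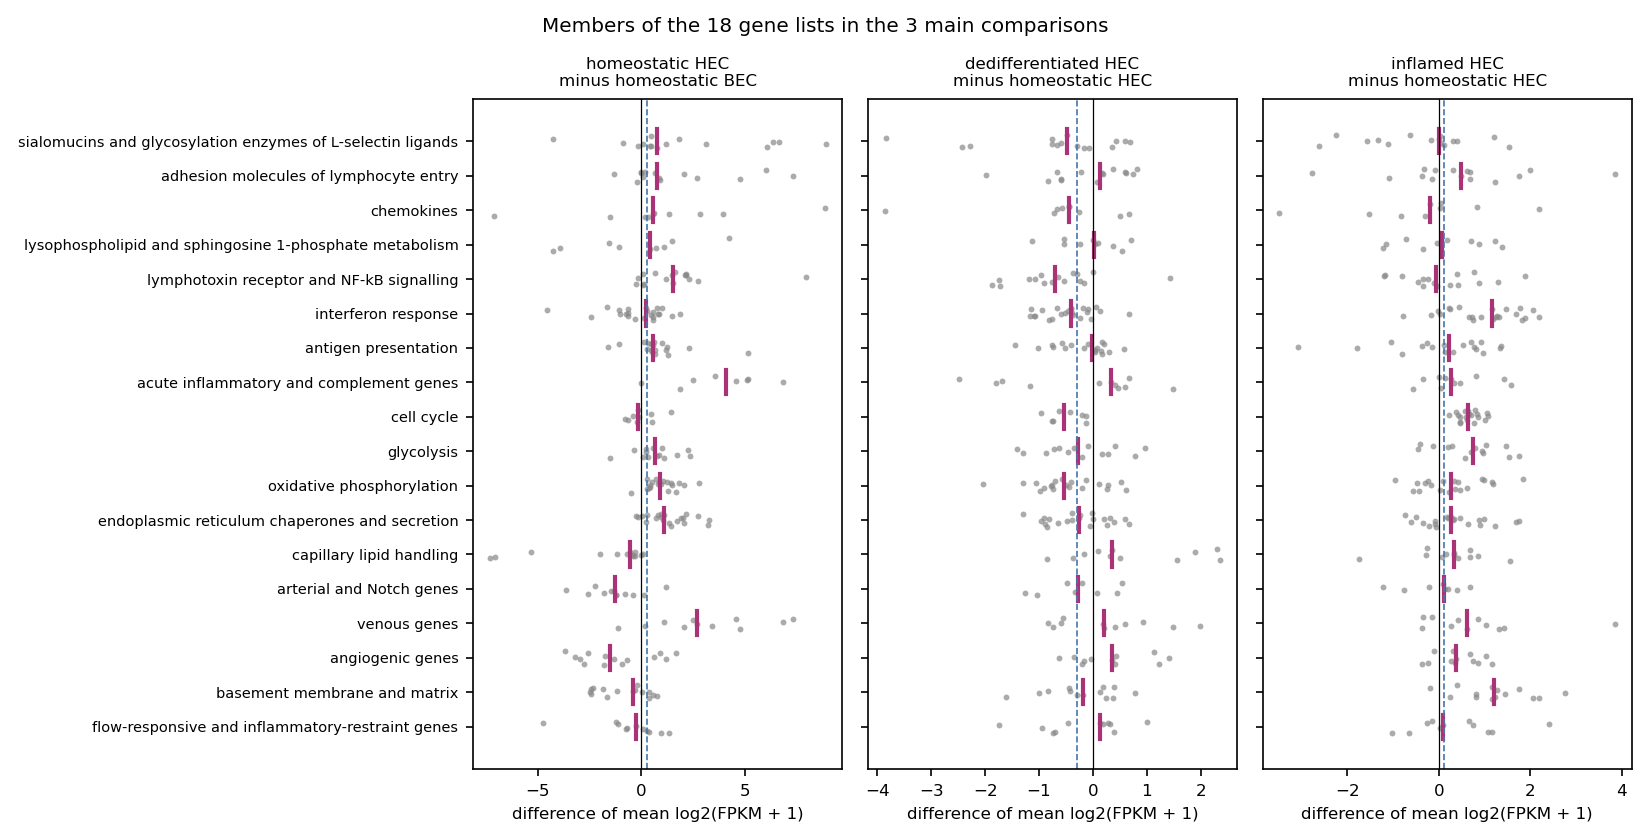
Difference of mean log2(FPKM + 1) for the members (grey points) of 18 gene lists in the 3 main comparisons, with the list median (magenta line), the median of all genes (dashed line) and 0 (solid line). The interferon median was 0.22, -0.42 and 1.17 from left to right, and the NF-kB median 1.52, -0.71 and -0.07.

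Both treated groups lay nearer to homeostatic HEC than to BEC. These cells had been sorted as HEC by a gate that is not given. How far the sort itself set this distance was not tested. On a scale from 0 at homeostatic HEC to 1 at BEC, built from genes chosen on odd-numbered cells and measured on even-numbered HEC and BEC, the 50 genes higher in HEC placed dedifferentiated HEC at 0.213 ± 0.212 (SD over cells, n = 44) and inflamed HEC at 0.130 ± 0.217 (n = 64). The 50 genes higher in BEC placed them at 0.024 ± 0.228 and 0.095 ± 0.251, and in cells matched on gene number at 0.089 and 0.053, so the order of the treated groups on the BEC genes turned. Against BEC, Ccl21a was higher by 9.38 in dedifferentiated and 7.34 in inflamed HEC, Ackr1 by 7.52 and 7.96, Glycam1 by 6.49 and 6.29, Chst4 by 5.62 and 6.71, Fut7 by 4.35 and 5.06, and Gcnt1 by 2.25 and 3.84. Cxcl12 was at -6.47 and -7.08, Gpihbp1 at -6.76 and -7.02, Rgcc at -8.17 and -6.63, Cd36 at -5.71 and -5.02, and the growth factor receptor Kdr at -2.37 and -2.39. The collagen Col4a1 was at -3.42 in dedifferentiated and -0.68 in inflamed HEC, and Selp was 6.53 above BEC in inflamed HEC. Fabp4 was 1.17 above BEC in dedifferentiated HEC, but at -0.09 in odd-numbered cells alone. Assigned to the nearest group mean with the cell itself left out, 32 of 32 BEC, 69 of 79 homeostatic HEC, 57 of 64 inflamed HEC and 35 of 44 dedifferentiated HEC (79.5%, 64.7% to 90.2%) fell in their own group, and 7 dedifferentiated HEC lay nearest to homeostatic HEC.

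**Figure D3:**
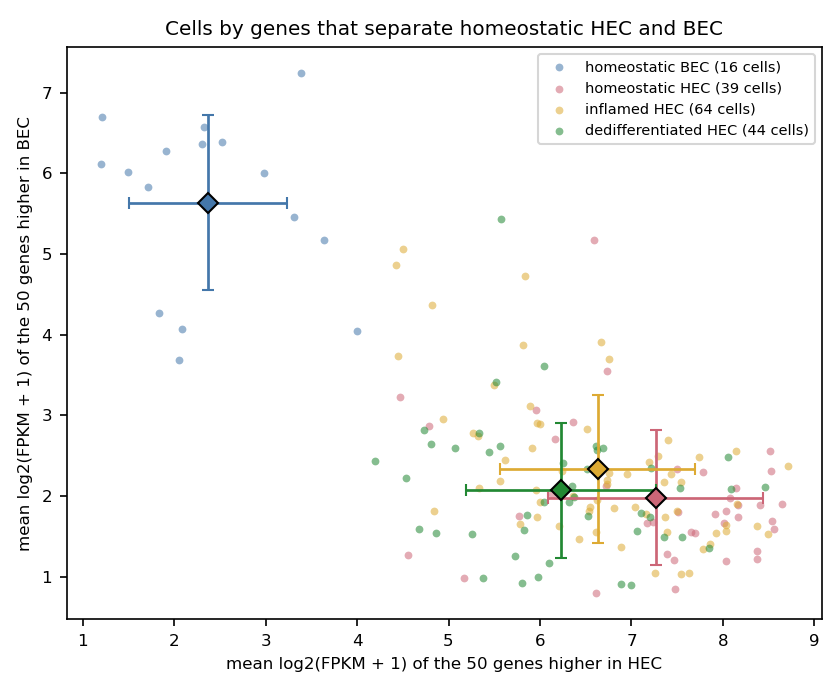
Each cell by its mean log2(FPKM + 1) over the 50 genes higher in HEC (horizontal) and the 50 genes higher in BEC (vertical), for the 16 BEC and 39 homeostatic HEC not used to choose the genes and all 64 inflamed and 44 dedifferentiated HEC; diamonds and bars are means and SD over cells. On the HEC genes the means were 7.27 in homeostatic, 6.63 in inflamed and 6.23 in dedifferentiated HEC and 2.37 in BEC.

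The series also asks how much high endothelial cells differ among themselves. Among homeostatic HEC, chemokines of the interferon response were among the genes that varied most in FPKM, through high values in few cells. Cxcl9 and Cxcl10 had a median FPKM of 0.2 and 0, a mean of 169.4 and 204.5, and a 90th percentile of 133.3 and 507.3. The 7 homeostatic HEC with markers of another cell type were kept here. The largest coefficients of variation among 1478 genes with a mean FPKM of 50 or more, whose median was 1.38, were those of Stmn1, a tubulin regulator of dividing cells (4.79), the interferon-induced chemokines Cxcl9 (4.59) and Cxcl10 (4.56), Itpripl1 (3.87), Bhlhe40 (3.87), Ptgds (3.73), Reg3g (3.56), Ifi27l2a (3.42), Thrsp (3.34) and Raet1e (3.31). Cxcl9 reached an FPKM of 1 in 30.4% of the 79 cells, and Cxcl1 in 67.1% (55.6% to 77.3%), with a coefficient of 2.02. By this measure, which was not corrected for level, abundant high endothelial genes varied less, with 0.913 for Glycam1, 0.740 for Ccl21a, 0.971 for Fut7, 0.910 for Gcnt1 and 1.15 for Chst4, yet over a wide range: Glycam1 had a 10th percentile of 3180 and a 90th percentile of 173714 FPKM over cells. Some less abundant members of the sialomucin and glycosylation list lay above the median of 1.38, with B3gnt3 and St3gal4 at 1.88, Parm1 at 3.78, Slc35c1 at 4.26 and Fut4 at 4.35. Others lay below it, with B4galt1 at 0.827, Chst2 at 1.06 and St3gal6 at 1.19. Parm1, Slc35c1 and Fut4 had a mean FPKM under 50 and so lay outside the genes that gave this median. Among adhesion genes, Pecam1 had a coefficient of 0.623, Icam1 of 1.25, Selp of 1.70, Vcam1 of 1.89 and Sele of 3.42, and Enpp2, at 0.476, was lower than these.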

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

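Chosen only after results were seen were the cells matched on gene number, the totals without Glycam1 and Ccl21a, the near-identical inflamed cells kept apart, and the tolerance of 0.1 below which a move of a list median was passed over, which shortened the list of medians given here. Of 261 named gene differences, 235 had a size of 1 or more, and 2664 of their 2670 alternative values kept their sign. Many of these genes were picked for large differences in the same cells that the alternatives reuse, so this count is no independent support. St3gal6 between HEC and BEC (1.21) turned to -0.14 as a ratio of arithmetic means and -0.18 in matched cells. Fabp4 between HEC and BEC (-1.19) turned to 0.33 in even-numbered cells, and between dedifferentiated HEC and BEC (1.17) to -0.090 in odd-numbered cells. Ccl21a between inflamed and homeostatic HEC (-1.53) turned to 0.042 in even-numbered cells, and Car4 between dedifferentiated and homeostatic HEC (1.55) to -0.53 as a ratio of arithmetic means. The cause was not tested for any of these or for the moves below, except that odd- and even-numbered sets hold fewer cells.

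Between HEC and BEC, the median of all genes, 0.28, became 0.13 with median ratios. The sialomucin median of 0.79 became 0.43 with a pseudocount of 10, 1.53 with the stricter filter, 0.39 with median ratios, 1.19 in odd-numbered cells and 0.38 in matched cells. The NF-kB median of 1.52 became 0.68 with a pseudocount of 10, 0.88 with arithmetic means and 0.998 in matched cells. The endoplasmic reticulum median of 1.09 became 0.63 with median ratios and 0.58 with arithmetic means, and the arterial median of -1.29 became -2.35 and -0.61 with pseudocounts of 0.1 and 10 and -2.49 with arithmetic means.

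Between dedifferentiated and homeostatic HEC, the sialomucin median of -0.48 became -0.25 with a pseudocount of 10, -0.27 with median ratios, 0.11 with arithmetic means, -0.11 in even-numbered cells and 0.044 in matched cells, and the NF-kB median of -0.71 became -0.34 with a pseudocount of 10. Between inflamed and homeostatic HEC, the sialomucin median, near 0, became -0.32 with the stricter filter, -0.11 with median ratios, -0.39 with arithmetic means, -0.10 without cells of unusual gene number, -0.14 in odd-numbered cells, -0.49 in matched cells and -0.11 without Glycam1 and Ccl21a in the total. The interferon median of 1.17 became 0.61 with a pseudocount of 10, 0.44 with arithmetic means and 0.53 in even-numbered cells. The cell cycle median of 0.65 became 1.09 and 0.22 with pseudocounts of 0.1 and 10 and 0.39 in even-numbered cells, and the matrix median of 1.19 became 0.56 with a pseudocount of 10.

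Over all lists, 94 of 273 alternative medians between HEC and BEC, 106 of 273 between dedifferentiated and homeostatic HEC and 71 of 294 between inflamed and homeostatic HEC moved by over 1.5 times and over 0.1, so medians not given here are not all stable. The capillary lipid median in dedifferentiated HEC, 0.34, became 0.89 and 0.13 with pseudocounts of 0.1 and 10, 0.23 without a filter, 1.72 with the stricter filter, 0.60 in even-numbered cells and 0.52 in matched cells.

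On the genes higher in BEC, the position of dedifferentiated HEC, 0.024, became -0.029 with 100 genes, 0.0052 with even-numbered cells choosing, 0.057 with median ratios and 0.089 in matched cells, and that of inflamed HEC, 0.095, became 0.053 in matched cells. With 2 markers sufficing, 10 BEC, 14 homeostatic HEC and 22 inflamed HEC carried markers of another type, and with markers at an FPKM of 1 it was 3 BEC, 13 homeostatic HEC, 9 inflamed HEC and 3 dedifferentiated HEC (from 1, 7, 3 and 2). At other detection limits, 69 of 112 shares of cells left the interval of the share reported, so shares hold for an FPKM of 1 at these depths only. No paired analysis was possible because the cell numbers that groups share only name a cell, and no comparison has a test.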

Other observations

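The tests of gene number in dedifferentiated HEC, for the immediate early genes and for the lipid genes, and of capillary cells in their sort were chosen only after the result was seen. For 2 enzymes of L-selectin ligands, chosen after their values were seen, the median cell of dedifferentiated HEC lay proportionally further below homeostatic HEC than the 90th percentile did. Gcnt1 had a median FPKM of 0.65 and a 90th percentile of 180.3 in dedifferentiated HEC (n = 44), against 132.9 and 360.7 in homeostatic HEC (n = 79). Fut7 had a median of 44.2 against 322.8 and a 90th percentile of 656.3 against 1086. Glycam1 had a median of 7027 in dedifferentiated, 6350 in inflamed and 59091 in homeostatic HEC, and its coefficient of variation was 1.58, 1.45 and 0.913. Ccl21a, in contrast, had a median of 64279 in dedifferentiated, 21032 in inflamed and 57488 in homeostatic HEC.

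Some genes, picked after their values were seen, differed from homeostatic HEC in the same direction in both treated groups, with the dedifferentiated value given first. Higher in both were Mustn1 (1.90 and 3.37), Aqp1 (1.89 and 1.56), Lrg1 (1.48 and 1.43) and Tnfrsf1a (1.43 and 1.29), and lower in both were Cxcl1 (-3.86 and -3.49), Jam3 (-1.99 and -2.78) and Pf4 (-3.20 and -2.20). Other genes lay on opposite sides: Nid1 (-1.61 and 1.46) and Irf7 (-1.15 and 1.78). Both comparisons share the homeostatic HEC, so common differences include the chance values of those cells.

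The 10 immediate early genes among the dissociation markers had a median difference from homeostatic HEC of -2.23 in inflamed and -0.91 in dedifferentiated HEC. Inflamed HEC had a higher median number of detected genes than homeostatic HEC (3961 against 3842), which argues against fewer detected genes as the cause there, and in cells matched on that number the median difference was -2.25 (-1.24 in odd-numbered and -3.38 in even-numbered cells). In matched dedifferentiated cells it was -0.69, but -0.13 in odd-numbered cells alone, so gene number cannot be told apart from other causes in that group; under the limit first written it would have counted towards gene number, and the limit was moved once the medians over all cells had been seen. A dissociation or sort that stressed the homeostatic HEC more stays open, because the 4 heat shock genes had medians of 0.32 in inflamed and 0.027 in dedifferentiated HEC, between the limits set for either answer, and day and chip follow the groups. An effect of oxazolone or LTBR-Ig on these genes also stays open and was not tested apart from them.

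Glycam1 and Ccl21a were present at a low level in every BEC, at 0.123% and 0.107% of their mean FPKM in homeostatic HEC. The 3 BEC with the most Glycam1 held 30.7% of its sum over the 32 BEC, which argues against whole high endothelial cells captured together with some BEC. Carry-over of RNA or reads from homeostatic HEC is consistent with the Glycam1 and Ccl21a values, since 0 of 280 genes with a mean FPKM of 300 or more in those cells lay in BEC under 50% of the level that the Glycam1 ratio predicts. Chst4 (0.538 against 0.484 predicted), Oit1 (0.563 against 0.405) and Serpina1e (1.24 against 1.77) lay near the predicted level, whereas Ubd (28.8 against 7.20, and 22.3 without its highest BEC) lay above it, as did Fut7 (5.54 against 0.505) and Pglyrp1 (5.17 against 1.70), in each of which 1 BEC made most of the gap (0.713 and 1.32 without it). With inflamed HEC as the source 3 of 321 genes lay under 50% of their predicted level, with dedifferentiated HEC 1 of 300, and the test rests on few genes, since 6 of the 280 had a BEC mean under 1% of that in homeostatic HEC, and low transcription in the BEC themselves stays open and was not tested.

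In dedifferentiated HEC, Fabp4, Fabp5, Aqp1 and Car4 were higher than in homeostatic HEC, as 4 of 11 members of the capillary lipid handling list, and so was Apoe, outside that list. No dedifferentiated cell had less than 2.86 of Fabp4 as log2(FPKM + 1), whereas 67 of 79 homeostatic HEC reached an FPKM of 1. Low values in place of 0 add to a difference on this scale. The mean FPKM of Fabp4 was 1737 against 799.9, a ratio of 2.17. Carry-over of RNA or reads was not tested for these genes. The 4 members chosen on odd-numbered cells had a median of 1.96 in even-numbered cells matched on gene number (Gpihbp1 among them 0.11). For the 4 chosen on even-numbered cells the median was 2.05 in the matched odd-numbered ones. Both medians argue against the number of detected genes as the cause, as far as the match goes. Matched dedifferentiated HEC still had a median of 3151.5 detected genes, against 3422 in matched homeostatic HEC. Fabp5 and Apoe lay above the higher of the HEC and BEC means by at least 1.48 in all, odd-numbered, even-numbered and matched cells. No mixture of homeostatic HEC with BEC at their mean gives that level for these 2 genes. Fabp5 and Apoe were set apart from Fabp4, Aqp1 and Car4 after the values had been seen. The outcome was therefore set by that choice and is no independent evidence against BEC in the sort. A capillary subset of the BEC with more of these genes than the mean was not tested. For Fabp4, Aqp1 and Car4 capillary BEC cannot be told apart from other causes: on the 50 genes higher in BEC, of which 25 were above homeostatic HEC, the position was 0.024 but 0.089 in matched cells, near the limit of 0.1, the blood endothelial markers lay 0.80 above the median of all genes, and Cd36 (-0.37) and Rgcc (-0.86) were lower in the mean while Cxcl12 (0.66) and Gpihbp1 (0.32) were higher. A response of HEC to LTBR-Ig stays open as a hypothesis beside a difference of chip or day, and neither was tested.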
